A study of Homo sapiens with 21 samples.

How the data were processed

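ChIP-seq of H3K27ac was analysed in 13 samples of 8 cell types, beside 5 inputs and 3 samples of H3K4me1. The inputs were of DE, PP1, PP2, EN and SC-beta, with none labelled for PH, Alpha or Beta. Lists of cell types with and without an input sample were thus compared, and the effect of this was not tested. Only the deposited lists were read here, so no input was used directly. The H3K4me1 samples entered no list used here. The labels name the 2 primary cell types as primary adult cells and also carry the name of the stem cell line, which was not resolved; they were treated as primary cells. Per the labels' protocols, cells were fixed and sorted before chromatin was sheared and precipitated.

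The authors deposited, for each cell type, a list of super-enhancers and a list of typical enhancers, with chromosome, start, end and a name for each region. Per the submitters' processing notes, Bowtie2, MACS2 and bedtools were used on hg19; their versions, settings and order are not given in the sources used here, nor is the rule that separated SEs from TEs or the way replicates were combined. The deposited regions hold no score, read count or fold, so the depth behind a region and a ranking within a list were unknown. Within a list, regions lay at least 12501 bp apart. Lengths alone did not separate the classes, since SEs were as short as 2.01 kb in DE and TEs as long as 98.7 kb in Beta. A merged catalogue of 34781 domains joined the regions of all lists, and each of the 26178 domains without a region of the prefix S0 had the outermost ends of its regions.

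Files were read as deposited, with no filter, and all columns of values were matched to a cell type. A region counted as present in another list when at least 1 bp overlapped, and it was given the status SE when it overlapped an SE, TE when it overlapped TEs only, and none otherwise. The Jaccard index was the number of groups of overlapping SEs with members of both lists over the number of all groups. Shares have 95% Wilson intervals. The order of 5 stages was tested by an exact permutation of 120 orders. SC-beta and PH were compared by exact McNemar (binomial) tests over regions present in only 1 of the 2 lists, and classes by the Fisher exact test, all two-sided. Benjamini-Hochberg adjustment covered 10 tests of the stage 6 populations and, apart from these, 8 tests of SEs against TEs of like length. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and the plots matplotlib 3.10.9.

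The functions were tested on simulated data. In 3 simulated pairs of lists the shared number came back exactly. In 1000 simulations of 212 regions, the number of Beta-selective SEs, the exact McNemar test called 3.2% without a difference. It called 91.8% with shares of 15% and 5%. The simulated lists were independent of each other. In the data, SC-beta and PH shared many of these regions, at shares of 66.0% and 64.2%, or 22.6% and 8.02% for SEs alone. The simulated rates therefore do not carry over to those tests.

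The main tests and their alternatives were chosen before the data were examined. Chosen afterwards were the odds ratios between the classes, the tests over EN, SC-beta and PH SEs, the length-matched comparison of SEs with TEs, the alternatives for the EN SEs kept, the setting without the shortest length quartile, the equal number of 3311 enhancers for the in vitro lists and the chromosome 17 map. The alternatives were an overlap of 50% of the shorter region, the 220 longest SEs of each list, autosomes only, SEs of at least 20 kb, SEs alone or with TEs as presence, and primary SEs without any enhancer in the other primary cell type.

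Regions were named by a rule fixed beforehand, the 3 longest SEs of each list without an enhancer in the other for each comparison, and the 5 longest SEs of each list. For the steps between stages and the description of lists, the text gives the longest of these; the chromosome 17 locus, within the rule, was picked after its values were seen, as were the longest SEs behind the counts of SC-beta alone and PH alone. A gene annotation on hg19 was not used here, so regions carry positions and no gene names, and it is not stated whether they are genic. For that reason 3 planned results were not run, those on gene lists near SEs, on core clock genes and on alpha and beta cell genes, and the circadian question in the series title was not addressed here.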

Results

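Enhancer activity was mapped by ChIP-seq of H3K27ac, a histone mark of active enhancers and promoters, in 8 human cell types on the path from stem cells to pancreatic islet cells. The series title names circadian control of islet maturation in vitro. The 6 in vitro cell types were made from HUES 8, a human embryonic stem cell line. They were definitive endoderm (DE, stage 1 day 3), the pancreatic progenitors PP1 (stage 3 day 2) and PP2 (stage 4 day 5), endocrine progenitors (EN, stage 5 day 3), and 2 populations of stage 6 day 8, stem cell-derived beta cells (SC-beta) and poly-hormonal cells (PH), which express more than a single islet hormone. The 2 primary cell types were adult alpha cells (Alpha), which secrete glucagon, and adult beta cells (Beta), which secrete insulin. The H3K27ac samples numbered 2 each in DE, PP1, EN, SC-beta and PH and 1 each in PP2, Alpha and Beta. With 5 input samples and 3 of H3K4me1, a mark of enhancers, the series held 21 samples.

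Each cell type had 1 deposited list of super-enhancers (SEs, large clusters of enhancer signal) and 1 of typical enhancers (TEs). A list stood for all samples of its cell type, so there were no replicate lists and no spread between replicates. Regions carried no read count or score, and the sequencing depth was unknown. Intervals below are 95% Wilson intervals that cover the counting of regions only, and tests compare these lists, with regions as units, not populations of cells or donors. Positions are on hg19.

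The size of the enhancer catalogue differed widely between the cell types. EN had 614 SEs and 12940 TEs, the most enhancers of the 8 lists, and the stage 6 populations that follow it had the fewest, 261 SEs and 3050 TEs in SC-beta and 220 SEs and 3507 TEs in PH. EN thus listed 4.09 times as many enhancers as SC-beta and 3.64 times as many as PH. Primary cells had long catalogues again, with 561 SEs and 10603 TEs in Alpha and 534 SEs and 7425 TEs in Beta. The earlier stages had 594 SEs and 5543 TEs (DE), 298 SEs and 5539 TEs (PP1) and 624 SEs and 8303 TEs (PP2).

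SEs were shortest in DE, with a median of 9.08 kb, and longest in Alpha, with 38.4 kb. The medians of the others were 12.2 kb in SC-beta, 14.2 kb in PP1, 15.6 kb in PP2, 19.2 kb in PH, 23.4 kb in Beta and 25.8 kb in EN. Enhancers covered 90.4 Mb in Alpha, 79.5 Mb in EN and 46.9 Mb in Beta, against 11.9 Mb in SC-beta and 16.5 Mb in PH. The share of these bases in SEs lay between 22.7% (EN) and 34.0% (DE). The longest SE of each list was chr6:2901514-2952693 in DE (51.2 kb), chr3:71177447-71299282 in PP1 (121.8 kb), chr14:68627567-68724118 in PP2 (96.6 kb), chr4:140646333-140865064 in EN (218.7 kb), chr1:27845291-27899585 in SC-beta (54.3 kb), chr8:118146465-118218377 in PH (71.9 kb), chr19:38396214-38626376 in Alpha (230.2 kb) and chr10:80818996-80950662 in Beta (131.7 kb). The PH region was also an SE in Alpha and Beta, and a TE in SC-beta, EN, PP1 and PP2. A locus on chromosome 17 was among the 5 longest SEs in 4 lists, as chr17:2746848-2944221 in EN, chr17:2786218-2844396 in PH, chr17:2731459-2935508 in Alpha and chr17:2714416-2844470 in Beta. It held SEs in SC-beta too, and TEs without an SE in DE, PP1 and PP2.

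**Figure D1:**
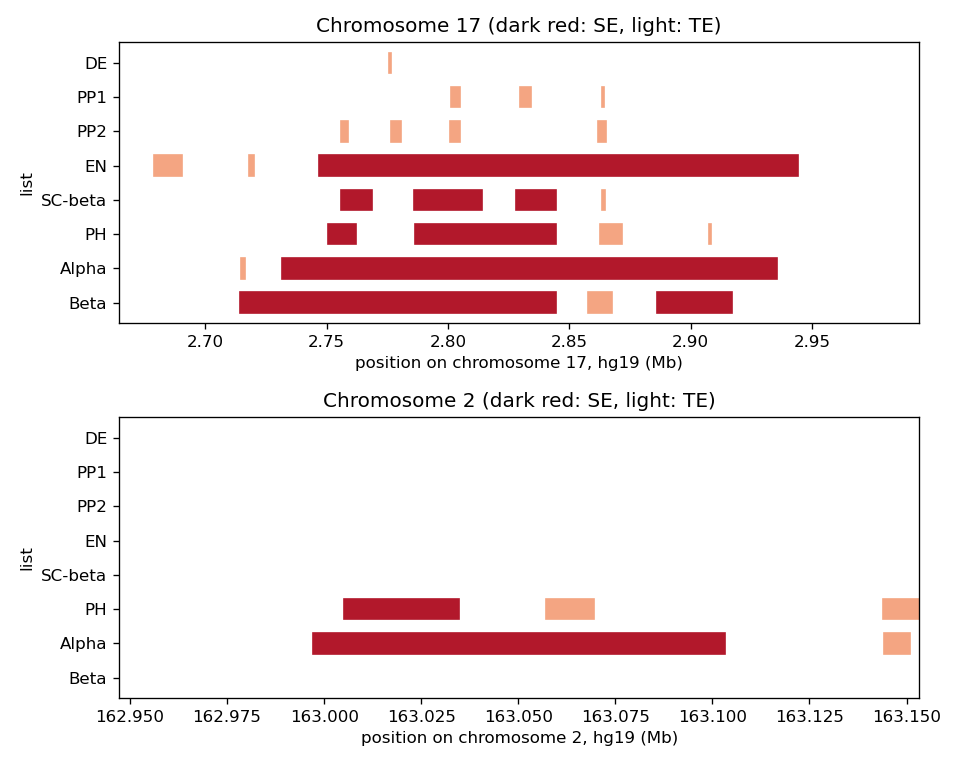
Listed regions by position (horizontal axis, hg19 in Mb) in each of the 8 lists (vertical axis); dark bars are SEs and light bars TEs. The upper panel holds the chromosome 17 locus, an SE in EN, SC-beta, PH, Alpha and Beta, and the lower panel the chromosome 2 region that was an SE in PH and Alpha and had no enhancer in Beta, SC-beta or the earlier stages.

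SE lists were then compared pair by pair, to ask which cell types shared their large enhancers. In the SE lists as deposited, the Jaccard index (shared groups of overlapping SEs over all groups) was 0.408 between Alpha and Beta and 0.380 between SC-beta and PH, the highest of the 28 pairs. Their order turned with the 220 longest SEs of each list, at 0.288 for Alpha and Beta and 0.408 for SC-beta and PH, and over all enhancers, at 0.446 and 0.516. SC-beta had a higher index with Beta (0.272) than with Alpha (0.197), also over all enhancers (0.253 and 0.199). By number of groups over all enhancers, it shared 2253 with Beta and 2375 with Alpha. The Alpha list was longer, with 11164 enhancers against 7959 in Beta, so the order over all enhancers depends on list size. PH had 0.229 with Alpha and 0.208 with Beta for SEs, and the reverse order over all enhancers, 0.240 with Alpha and 0.261 with Beta. The number of groups shared over all enhancers was 2842 with Alpha and 2396 with Beta. This reversal of the index thus depends on list size and does not show PH closer to Beta. PP1 and PP2 had an index of 0.270, and the values of DE ran from 0.051 with Alpha to 0.149 with PP2.

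Along the 5 stages DE, PP1, PP2, EN and SC-beta, the mean index was 0.194 for the 4 neighbouring pairs and 0.129 for the other 6 pairs. The rank correlation of the index with the number of steps between stages was -0.693, with a two-sided exact permutation p of 0.0333 over the 120 orders of the stages, where 0.0167 is the smallest p possible. With only 5 stages this describes their order and does not stand for other differentiations. With the 220 longest SEs of each list, the correlation was -0.598 and the exact permutation p was 0.0833.

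**Figure D2:**
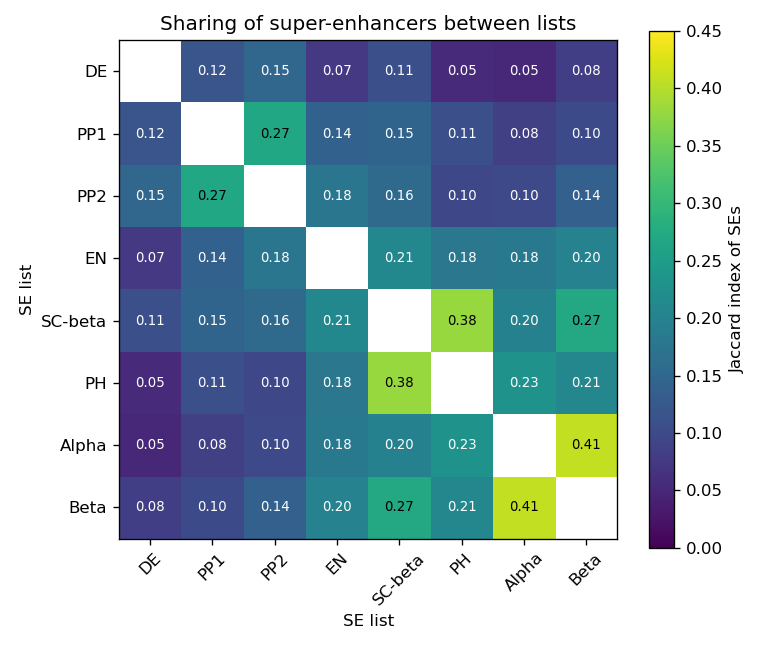
Jaccard index of SEs (colour and number in each cell) for every pair of the 8 SE lists, given on both axes. Alpha and Beta (0.408) and SC-beta and PH (0.380) had the highest values for the lists as deposited, and DE had at most 0.149 with any other list.

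The fate of SEs at each step of differentiation was read from their status in the next list. Between DE and PP1, 96 of 594 DE SEs stayed SEs (16.2%, 13.4 to 19.3), 279 overlapped TEs only and 219 overlapped no enhancer of PP1 (36.9%, 33.1 to 40.8). In PP2, which listed 624 SEs against 298 in PP1, 162 of the DE SEs were SEs (27.3%, 23.8 to 31.0). The lower share in PP1 thus does not show a lasting loss, and it may depend on list size. Between PP1 and PP2, 200 of 298 SEs stayed SEs (67.1%, 61.6 to 72.2) and 11 overlapped no enhancer (3.69%, 2.07 to 6.49). Between PP2 and EN, 188 of 624 SEs stayed SEs (30.1%, 26.7 to 33.8), 364 overlapped TEs only and 72 no enhancer. Of the 614 EN SEs, 151 were SEs in SC-beta (24.6%, 21.4 to 28.2) and 126 in PH (20.5%, 17.5 to 23.9), while 178 and 188 overlapped no enhancer there.

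Nearly all SEs of the stage 6 populations lay where EN already had an enhancer. In SC-beta, 156 of 261 SEs overlapped an SE of EN (59.8%, 53.7 to 65.5), 96 a TE only and 9 no enhancer. In PH, 128 of 220 overlapped an SE of EN (58.2%, 51.6 to 64.5), 82 a TE only and 10 no enhancer. This was not particular to EN, since 253 of the 261 SC-beta SEs overlapped an enhancer of PH and 248 one of Beta, against 252 for EN. Of the 614 EN SEs, 174 (28.3%, 24.9 to 32.0) overlapped none of the 8927 enhancers of PP2, a shorter list than the 13554 of EN. Among EN SEs, 52 were SEs in SC-beta and not in PH and 27 the reverse (two-sided exact McNemar p = 0.00655, adjusted 0.00936 over 10 tests). SC-beta had the longer SE list, and the difference did not pass the test with the 220 longest SEs of SC-beta and PH (43 and 31, exact p = 0.201). It did not pass with the 220 longest SEs of EN as well (14 and 12, exact p = 0.845), nor with TEs counted (54 and 44, exact p = 0.363, adjusted 0.404).

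The longest DE SE without an enhancer in PP1 was chr2:47948069-47988260 (40.2 kb), which overlapped no enhancer of any other list. The longest PP1 SE without one in DE was chr6:20852472-20894148 (41.7 kb), an SE in PP2 and EN as well. The longest PP1 SE without an enhancer in PP2 was chr6:26155801-26208174 (52.4 kb). It was an SE in DE and a TE in EN, SC-beta, PH, Alpha and Beta, so it was missing from the PP2 list alone. The longest PP2 SE without an enhancer in PP1 was chr4:79105428-79142228 (36.8 kb), a TE in DE. The longest PP2 SE without an enhancer in EN was chr1:120555067-120613346 (58.3 kb), a TE in DE and PP1. In the other direction, the longest EN SE without one in PP2 was chr10:35667506-35761009 (93.5 kb), also a TE in DE. The longest EN SE without an enhancer in SC-beta was chr14:85993408-86068421 (75.0 kb), which had none in PH or Alpha and was an SE in PP1 and PP2. The longest EN SE without one in PH was chr20:20375906-20480755 (104.9 kb), an SE in Beta. The longest without one in EN were chr19:59073379-59087743 in SC-beta (14.4 kb), a TE in PP2 and an SE in PH and Beta, and chr2:163005030-163034654 in PH (29.6 kb).

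With the 220 longest SEs of each list, which equalises their number and leaves out short SEs, the shares that stayed SEs were 14.5% from DE to PP1, 37.3% from PP1 to PP2, 22.7% from PP2 to EN, 28.2% from EN to SC-beta and 27.3% from EN to PH.

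Mature beta cell SEs were looked up in SC-beta, to see how much of the adult pattern the in vitro cells held. Of the 534 Beta SEs, 169 were SEs in SC-beta (31.6%, 27.8 to 35.7), 243 overlapped TEs only and 122 overlapped no enhancer (22.8%, 19.5 to 26.6). Counting SE or TE, 77.2% (73.4 to 80.5) were present in SC-beta, 79.0% (75.4 to 82.3) in PH and 88.2% (85.2 to 90.7) in EN. At the earlier stages the share was 40.3% (36.2 to 44.5) in DE, 52.8% (48.6 to 57.0) in PP1 and 70.6% (66.6 to 74.3) in PP2. On the path from DE to SC-beta, 7 Beta SEs had their first listed enhancer in SC-beta and 92 in EN, and 28 had none at any of these 5 stages. SC-beta came last in this order, after the longer EN list, so few Beta SEs were left for it. These counts therefore do not date when the enhancers arose.

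The 3 longest Beta SEs without an enhancer in SC-beta were chr16:85634233-85715636 (81.4 kb), chr17:57430097-57503888 (73.8 kb) and chr1:207977909-208043339 (65.4 kb). Each was an SE in Alpha and overlapped a TE in PH. In the other direction, 13 of the 261 SC-beta SEs overlapped no enhancer of Beta, the longest of them chr11:1989941-2013414 (23.5 kb), an SE in PP1, PP2 and EN, chr3:186647958-186667080 (19.1 kb) and chr17:8042029-8060983 (19.0 kb). None of these 3 overlapped an enhancer of Alpha. Beta SEs were more often present in SC-beta than Beta TEs of like length. From 20 to 40 kb, 191 of 241 SEs (79.3%, 73.7 to 83.9) and 49 of 127 TEs (38.6%, 30.6 to 47.3) were present (two-sided Fisher exact p = 1.62e-14, adjusted 6.46e-14 over 8 tests). This was not particular to SC-beta, since EN held 215 of these SEs (89.2%) and 76 of these TEs (59.8%).

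Mature alpha cell SEs were looked up in PH in the same way. Of the 561 Alpha SEs, 144 were SEs in PH (25.7%, 22.2 to 29.4), 321 overlapped TEs only and 96 no enhancer (17.1%, 14.2 to 20.4). As SE or TE, 82.9% (79.6 to 85.8) were present in PH, 74.3% (70.6 to 77.8) in SC-beta and 88.1% (85.1 to 90.5) in EN. The share was 39.2% in DE, 50.6% in PP1 and 63.5% in PP2. From DE to PH, 19 Alpha SEs had their first listed enhancer in PH and 107 in EN, and 25 had none. PH came last in this order, so the same limit holds. From 20 to 40 kb, 185 of 226 Alpha SEs (81.9%, 76.3 to 86.3) and 263 of 575 Alpha TEs (45.7%, 41.7 to 49.8) were present in PH (two-sided Fisher exact p = 1.79e-21, adjusted 1.43e-20). Here too EN held more of the SEs, 189 (83.6%), than of the TEs, 376 (65.4%).

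The 3 longest Alpha SEs without an enhancer in PH were chr5:14382765-14472862 (90.1 kb), chr21:39164483-39242623 (78.1 kb) and chr5:166999915-167067172 (67.3 kb). Of the 220 PH SEs, 17 overlapped no enhancer of Alpha. The longest of these were chr10:45458684-45493022 (34.3 kb), chr17:27874772-27903019 (28.2 kb) and chr11:61351727-61379969 (28.2 kb), of which the first and last were SEs in Beta. Because EN had 13554 enhancers and SC-beta and PH had 3311 and 3727, the higher shares in EN were not taken from lists of like size.

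**Figure D3:**
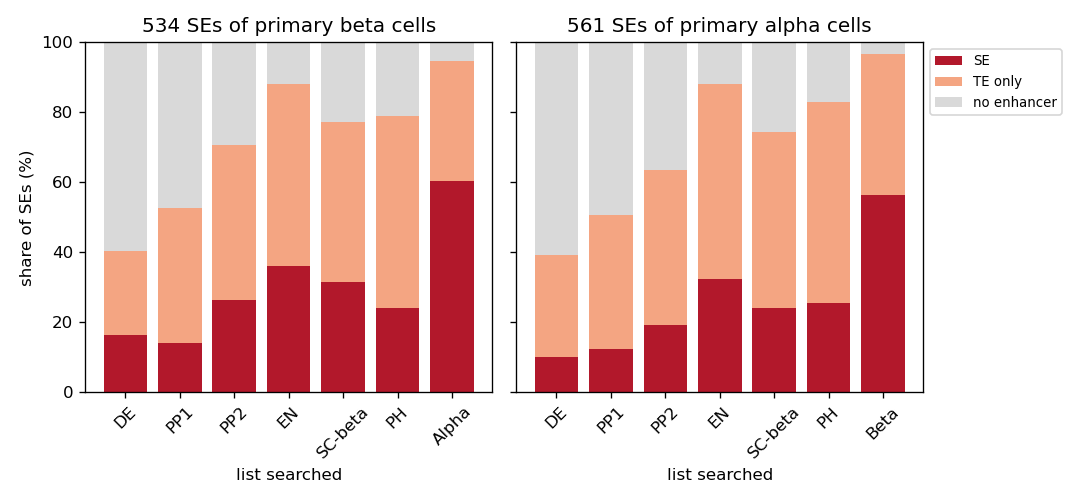
Share of Beta SEs (left, 534) and Alpha SEs (right, 561) in percent (vertical axis) that were SEs, overlapped TEs only or overlapped no enhancer in each other list (horizontal axis). The share with any enhancer was higher at each stage from DE to EN, was 88.2% for Beta SEs and 88.1% for Alpha SEs in EN, and was lower in SC-beta and PH.

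The primary lists were compared with each other before the in vitro populations were set against them. Of the Beta SEs, 322 were SEs in Alpha (60.3%, 56.1 to 64.4) and 29 overlapped no enhancer of Alpha (5.43%, 3.81 to 7.69). Of the Alpha SEs, 316 were SEs in Beta (56.3%, 52.2 to 60.4) and 18 overlapped none of Beta (3.21%, 2.04 to 5.01). The 3 longest of the 18 were chr2:162997155-163103333 (106.2 kb), chr17:70923896-71008214 (84.3 kb) and chr5:166999915-167067172 (67.3 kb). The first was an SE in PH and overlapped no enhancer in the other in vitro lists. The 3 longest of the 29 were chr11:61261599-61379276 (117.7 kb), an SE in EN, SC-beta and PH, chr17:17583787-17697268 (113.5 kb), an SE in PP1, PP2, EN and SC-beta, and chr17:76857223-76931607 (74.4 kb), a TE in EN, SC-beta and PH.

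SC-beta and PH were then compared at SEs of a primary cell type that overlapped no SE of the other, to ask which primary cell each resembled. Most of these regions were enhancers in both primary cell types. A TE of Beta lay at 227 of the 245 Alpha-selective SEs, and a TE of Alpha at 183 of the 212 Beta-selective SEs. An enhancer of PH or SC-beta there thus does not by itself mark a single primary cell type. PH listed more Alpha-selective SEs than SC-beta. Of the 245 SEs of Alpha that overlapped no SE of Beta, 45 overlapped an enhancer of PH and none of SC-beta, and 11 the reverse; 131 overlapped both (two-sided exact McNemar p = 5.38e-06, adjusted 1.79e-05). At the 212 SEs of Beta that overlapped no SE of Alpha, no difference passed the test. Here 25 overlapped an enhancer of SC-beta alone, 21 of PH alone and 115 of both (exact p = 0.659, adjusted 0.659). The difference between these classes had an odds ratio of 4.79 (1.87 to 12.99, two-sided Fisher exact p = 3.66e-04, adjusted 7.31e-04).

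When only SEs of SC-beta and PH were counted, a setting chosen beforehand, the Beta-selective class differed too. Of the 212 Beta-selective SEs, 33 were SEs in SC-beta alone and 2 in PH alone (exact p = 3.67e-08, adjusted 1.84e-07). The call rested on short regions, since 24 of the 33 lay in the shortest length quartile of the classes, up to 17.7 kb, and without it the numbers were 9 and 2 (exact p = 0.0654). Of the 245 Alpha-selective SEs, 5 were SEs in SC-beta alone and 23 in PH alone (exact p = 9.12e-04, adjusted 0.00152). An enhancer of SC-beta was thus present at 66.0% of Beta-selective SEs and one of PH at 64.2%, while 22.6% were SEs in SC-beta and 8.02% in PH. The longest Beta-selective SEs that were SEs in SC-beta and not in PH were chr17:17583787-17697268, chr22:19957336-20005307 and chr1:8221267-8263960, and each overlapped a TE in PH. The longest Alpha-selective SEs that were SEs in PH and not in SC-beta were chr3:50417594-50542179, chr6:138500972-138609085 and chr2:162997155-163103333, of which the last overlapped no enhancer of SC-beta.

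Seen from the in vitro side, 48 of the 261 SC-beta SEs overlapped an SE of Beta and not of Alpha, and 17 the reverse (exact p = 1.52e-04, adjusted 3.80e-04). Of the 220 PH SEs, 36 overlapped an SE of Alpha and not of Beta, and 18 the reverse (exact p = 0.0198, adjusted 0.0248). Alpha SEs covered more bases than Beta SEs (24.7 Mb against 14.3 Mb), and neither test was adjusted for this. With any enhancer counted, 206 PH SEs overlapped one of Beta and 203 one of Alpha. Of the SC-beta SEs, 248 overlapped an enhancer of Beta and 235 one of Alpha. Directly between the stage 6 lists, 8 SC-beta SEs overlapped no enhancer of PH and 21 PH SEs none of SC-beta. The longest were chr17:43047012-43070401 (23.4 kb), chr2:120179657-120196061 (16.4 kb) and chr6:43737225-43750774 (13.6 kb) in SC-beta, of which the first was a TE in both primary lists, the second a TE in Beta alone and the last an SE in both. In PH they were chr7:92822738-92855856 (33.1 kb), chr16:52578407-52609229 (30.8 kb) and chr2:163005030-163034654 (29.6 kb), all of them SEs in Alpha and none an SE in Beta. The classes differed in length, with a median of 18.3 kb for Beta-selective and 38.7 kb for Alpha-selective SEs. At primary SEs that overlapped no enhancer of the other primary cell type, 3 Beta SEs were found in SC-beta alone and 0 in PH alone, too few to pass the test (exact p = 0.25, the smallest possible), and 1 and 5 Alpha SEs (exact p = 0.219).

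**Figure D4:**
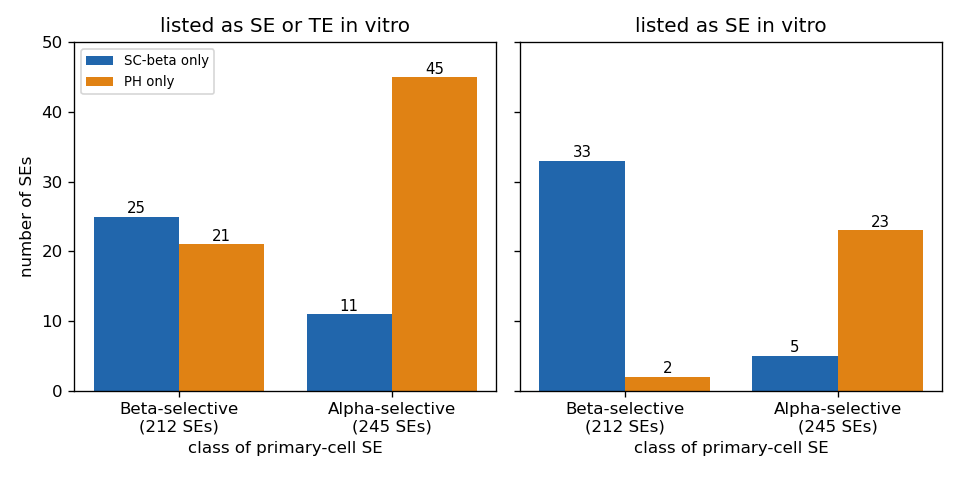
Number of Beta-selective (212) and Alpha-selective (245) SEs (vertical axis) found in SC-beta only or in PH only, counting SE or TE (left) or SE alone (right) in vitro. PH had the larger number at Alpha-selective SEs in both panels (45 against 11 and 23 against 5), and SC-beta had 33 against 2 at Beta-selective SEs on the right and 25 against 21 on the left.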

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

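In this part the odds ratios and the test with lists of equal size were chosen only after the result was seen; the comparison within length quartiles was chosen before, except that with TEs counted.

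The contrast between SC-beta and PH differed between the classes of primary SEs, since for SEs alone the odds ratio between Beta-selective SEs (33 in SC-beta only, 2 in PH only) and Alpha-selective SEs (5 and 23) was 66.9 (11.7 to 756, two-sided Fisher exact p = 2.42e-10, adjusted 2.42e-09). Different list sizes were argued against as the whole cause among the longest SEs, since the 220 longest SEs of each list gave an odds ratio of 20.6 (2.23 to 1052). This cut also took both classes from the 220 longest Alpha and Beta SEs, so it does not cover the short SEs. Different region lengths were argued against as the whole cause too, since the odds ratio pooled over length quartiles was 9.59 (1.77 to 52.0) for SEs and 6.30 (2.01 to 19.8) with TEs counted, where it was 4.79 without quartiles. The shortest quartile held 24 of the 33 Beta-selective SEs of SC-beta alone and no Alpha-selective SE of either list alone, so it added nothing to the pooled value for SEs, which was lower than 66.9. A resemblance of PH to alpha cells and of SC-beta to beta cells may explain the rest and stays open, as do the unknown depth and SE threshold of each list. SC-beta had an input sample and PH, Alpha and Beta had none, and the effect of this was not tested.

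In the merged catalogue, 5746 of 34781 domains (16.5%) held only regions with the prefix S0, which the comparisons of the 8 cell types did not use. The catalogue is named for 9 cell types, of which stem cells come first and have no list of their own here; no test of what these domains are was made.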

How the results depend on the processing

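The alternatives with 3311 enhancers, and all those of the odds ratios and of the EN SEs kept, and that without the shortest quartile, were added after the data were seen. Of 68 alternative values for 20 results, 46 kept the value or the call and none reversed. Those on autosomes only (20) and with an overlap of 50% of the shorter region (12) were all among them, and the odds ratio between classes passed its test in all 5 alternatives that gave a value. The cause was not tested for the changes that follow, unless the setting itself shows it.

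With the 220 longest SEs of each list, the rank correlation of sharing with steps was -0.598 (exact permutation p = 0.0833). Under that setting the share that stayed SE was 27.7% for Beta in SC-beta, 37.3% for PP1 in PP2, 22.7% for PP2 in EN, 28.2% for EN in SC-beta and 27.3% for EN in PH. Of EN SEs kept as SE in 1 of SC-beta and PH, SC-beta held 65.8% (exact p = 0.00655), against 53.8% with the 220 longest SEs of each list (p = 0.845), 58.1% with those of SC-beta and PH alone (p = 0.201) and 55.1% with TEs counted (p = 0.363). Counting TEs as present, by construction, gave 77.2% of Beta SEs in SC-beta and 82.9% of Alpha SEs in PH, and 77.2% and 80.0% with the 3311 longest enhancers. Counting only SEs in vitro, SC-beta held 94.3% of the Beta-selective SEs present in 1 of SC-beta and PH (exact p = 3.67e-08), against 54.3% with TEs and 81.8% without the shortest length quartile (exact p = 0.0654). At SEs with no enhancer in the other primary cell type, SC-beta held 16.7% of such Alpha-selective SEs (exact p = 0.219), where only 6 regions entered the test; the odds ratio there had no finite value (lower bound 0.694) and is left out. SEs of at least 20 kb numbered 76 in DE, 90 in PP1, 234 in PP2, 402 in EN, 68 in SC-beta, 103 in PH and 323 in Beta.

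No paired analysis was possible because each cell type had 1 list for all its samples, and for the same reason leaving out replicates was not run. The alternatives for gene lists, core clock genes and alpha and beta cell genes were not run, for want of an hg19 annotation. The depth was unknown, so absence from the short SC-beta and PH lists limits what can be said of single regions.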

Other observations

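In this part the tests on list sizes and on shared culture for the pairing by source were chosen only after the result was seen, and the descriptions of common and list-specific SEs were added after the lists were examined.

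A small core of SEs was shared by all cell types. From DE to the primary cells, 16 SEs of each list were SEs in all 8 lists, the longest in SC-beta being chr19:18390212-18416276 (26.1 kb), chr11:65243673-65269562 (25.9 kb), chr20:22541273-22566485 (25.2 kb) and chr15:93351563-93376520 (25.0 kb). With any enhancer counted, 113 of 261 SC-beta SEs (43.3%, 37.4 to 49.4) were present in all 8 lists, against 138 of 594 DE SEs (23.2%, 20.0 to 26.8) and 142 of 534 Beta SEs (26.6%, 23.0 to 30.5). This requires presence in SC-beta, the list with the fewest enhancers (3311), which SC-beta SEs meet by definition. It held an enhancer at 206 of the DE SEs and 412 of the Beta SEs, so the shares depend on list size. List-specific SEs, with no enhancer in any other list, were most numerous in DE, with 123 (20.7%, 17.6 to 24.1), and EN had 33, PP2 7, Alpha 3, Beta 3 and PP1 1. SC-beta and PH, the lists with the fewest enhancers, had none. The longest of each list were chr4:80083730-80134370 in EN (50.6 kb), chr8:19412947-19460587 in Alpha (47.6 kb), chr2:218762280-218809540 in Beta (47.3 kb), chr2:47948069-47988260 in DE (40.2 kb), chr5:5310688-5337304 in PP2 (26.6 kb) and chr17:46598707-46610742 in PP1 (12.0 kb).

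Few primary SEs lacked an enhancer in all 6 in vitro lists, 24 in Beta (4.49%, 3.04 to 6.60) and 23 in Alpha (4.10%, 2.75 to 6.08). The longest were chr2:132975192-133039655 (64.5 kb), chr19:3358000-3414868 (56.9 kb) and chr2:218762280-218809540 (47.3 kb) in Beta, of which the last was absent from Alpha too. In Alpha they were chr7:158030026-158089204 (59.2 kb), chr2:132986659-133039829 (53.2 kb) and chr10:79243284-79294495 (51.2 kb). Regions of the prefix S0 shared a merged domain with 55.2% of SEs in both DE (51.2 to 59.2) and SC-beta (49.1 to 61.1), 50.7% in PP1, 49.4% in PP2, 47.3% in PH, 42.7% in Beta, 38.8% in EN and 37.3% in Alpha (33.4 to 41.3). For TEs the shares were 31.2% in SC-beta, 28.2% in DE, 26.3% in PH, 21.5% in PP1, 17.8% in PP2, 16.1% in Beta, 12.4% in EN and 11.5% in Alpha. EN and Alpha, with the lowest shares of SEs and TEs, had the most enhancers, and SC-beta had the fewest. These shares may therefore depend on list size, which was not tested.

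The SC-beta list was far shorter than those of EN and Beta. Of the 3845 EN enhancers that Beta also listed, 1779 were missing from SC-beta (46.3%, 44.7 to 47.8). This was above the bound of 20% set beforehand for a lower sensitivity of the SC-beta list. However, SC-beta listed 3311 enhancers in all, fewer than 3845, so a short list makes a high missing share likely whatever the cause. The share thus cannot decide on a lower sensitivity, which may account for part of the difference and stays open. Enhancers of EN that close for good in beta cells cannot account for those 1779. They made up 16.5% (15.8 to 17.2) of the 10814 EN enhancers missing from SC-beta, a value between the bounds of 5% and 20% set beforehand, so for the rest it stays open. An enhancer that is silent in SC-beta and active again in adult beta cells would look the same as a missed one, and this was not tested.

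By the Jaccard index of SEs, SC-beta shared more with PH than with Beta, and Alpha and Beta more with each other than with any in vitro list. By share, 134 of the 261 SC-beta SEs were SEs in PH and 173 in Beta, whose SE list was longer. With the 220 longest SEs of each list, the Jaccard index of SC-beta with PH exceeded that with Beta by 0.246 (bootstrap over SC-beta SEs, approximated from shares, 0.169 to 0.317). This cannot decide on different list sizes, since the cut kept all 220 PH SEs and, of the 534 Beta SEs, only the longest. With the cut, the index of SC-beta fell from 0.272 to 0.163 with Beta and rose from 0.380 to 0.408 with PH. Over all enhancers the index with PH exceeded that with Beta by 0.264, with 3727 enhancers in PH and 7959 in Beta. By share, 253 of the 261 SC-beta SEs and 70.8% of the 3050 SC-beta TEs overlapped an enhancer of PH. For Beta the values were 248 and 68.6%, so the gap of 0.264 depends on list size too. Shared culture, laboratory or processing may also be a cause. It cannot be told apart from maturity, since all stage 6 cells came from culture and all mature cells were primary.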
